A study of Homo sapiens with 10 samples.

How the data were processed

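Total RNA of 10 libraries (2 per group) had been extracted with TRI reagent and a Direct-zol kit, depleted with GlobinClear and made into non-directional libraries with an NEB kit, per the labels. Per the submitters' processing notes, reads were called with CASAVA (version not given in the sources used here), aligned to GRCh38 (hg38) with STAR 2.5 and counted with HTSeq 0.6.1, and the authors tested differences with DESeq2, for which the notes give the version as 2. The annotation release is not given in the sources used here. The authors' deposited values are FPKM for 58735 genes in 10 columns, all mapped to samples.

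FPKM multiplied by gene length gave whole reads for 100% of values (tolerance 0.05). The reads in genes were 18063122 and 15703804 for DMSO, 17326722 and 16874950 for BLU667, 17238189 and 16570660 for BR8, 15243703 and 21904245 for BR10, and 16508915 and 17818517 for BR16. The deposited FPKM already carried the size factors of a median-of-ratios scaling, so that scaling anew moved next to nothing. The unit differs from the planned option for counts, which was not used because the deposited table held FPKM.

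The groups, comparisons, filter, test, named-gene rule, 33 gene lists (609 members) and first set of alternatives were fixed before the data were examined. Genes with FPKM of at least 1 in at least 2 libraries (13927) were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1) with a variance trend, in 1 fit of 5 groups with 5 residual degrees of freedom. Two-sided p were adjusted by the Benjamini-Hochberg method and called below 0.05. Adding 1 FPKM understates changes of low genes. The adapted colonies were compared as the mean of 3 group means, so that their SE reflects variation between libraries and not between colonies, and 3 colony means were also used as replicates. Differences among colonies used a moderated F test.

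Gene lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, with p adjusted over lists, and beside it with an estimated correlation and with fry. Immune, endothelial, erythroid, C cell and squamous lists had fewer tested members. Of the list symbols, 4 were found only through the reference gene ID. Counts adjusted over the list alone used the same gene-wise p within each list.

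RET, CCDC6, TERT and CDKN2A were named whatever their values. Others were named by rule: the 10 largest rises and falls per main comparison among called protein-coding genes with mean FPKM of at least 1 in a compared group, no overlap between libraries of the groups and, for adapted contrasts, the same sign in each colony; up to 4 called members per list; and per colony the 4 largest differences either way from the mean of the other two, called against both. Some genes that met this rule are not reported here. For a gene with 0 reads in a group, the fold is a floor with 3 reads over that group.

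Other settings chosen before the data were examined were pseudocounts of 0.1 and 0.25, no filter, FPKM of at least 5, median of ratios, quantile normalization, a replicate block, no variance trend, an absolute log2 change of at least 1, each library left out, only the groups compared, colony means as 3 replicates, estimated correlation and fry. Added after seeing the data were removal of each library's GC trend (loess, span 0.3), voom on recovered reads, array weights (equal within each pair, so that they weighted groups and not single libraries), and the adapted colonies without BR16.

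On 13222 simulated genes, BLU667 against DMSO recovered 55 of 95 tested genes changed 2-fold and 77 of 93 changed 4-fold, with 6 false calls. The adapted colonies against DMSO (13196 genes) recovered 71 of 93 and 87 of 96, with 10 false calls. Against BLU667 (13174 genes) they recovered 73 of 91 and 81 of 92, with 7. No simulated change got the wrong sign. In separate runs a shifted ERK list was found lower with 0 other lists called. Such runs do not vouch for data with GC trends or correlated genes. Python 3.11.15 with matplotlib 3.10.9 drew the figures.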

Results

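RNA was sequenced from TPC-1 cells, a papillary thyroid carcinoma line that carries a CCDC6-RET fusion, in 5 groups of 2 libraries each. Parental cells had received the solvent DMSO or 5 µM BLU667 (pralsetinib, an inhibitor of the RET kinase) for 24 h. The adapted colonies BR8, BR10 and BR16 had been grown from parental cells kept in 5 µM BLU667. The sample labels give that exposure as more than 50 days and the series design gives it as more than 5 months. Each library held between 15243703 and 21904245 reads in genes, and 13927 of 58735 genes reached the FPKM filter and were tested.

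Between replicates of a group, log2 values correlated across genes at r = 0.978 (DMSO) or more. The spread beyond counting error was largest in DMSO (chi-square per degree of freedom 24.1) and smallest in BR16 (2.59). Pooling these in 1 fit may understate SE against DMSO and overstate it among colonies. Genes are not independent replicates. The first 3 principal components held 38.9%, 27.5% and 17.6% of the variance. Mitochondrial reads made up 4.65% and 5.33% of the DMSO libraries, 6.49% and 4.44% in BLU667 and 5.52% and 5.31% in BR16. BR8 held 3.64% and 3.23%, and BR10 3.42% and 3.56%. Expression differences also followed the GC content of transcripts, with a Spearman correlation across genes of 0.62 between the DMSO replicates, -0.61 between BR8 and BR16 and -0.53 between BR10 and BR16. It was -0.13 for BLU667 against DMSO and -0.11 for the adapted colonies against DMSO, an average of opposite trends in BR8 (-0.29), BR10 (-0.25) and BR16 (0.26). Below, FPKM are group means ± SD (n = 2 libraries per group), log2 changes are ± SE of the limma fit, and colonies are given in the order BR8, BR10, BR16. A list's median is that of its tested genes' log2 changes. A dagger marks a gene overlapping another, whose reads this non-directional library could not assign by strand, so that its values are uncertain.

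RET, the kinase gene of the fusion (ENSG00000165731, GRCh38 chromosome 10, 43077027 to 43130351, plus strand), rose slightly in BLU667, from 6.91 ± 0.014 to 8.93 ± 0.58 FPKM (log2 change 0.33 ± 0.073, adjusted p = 0.00471). The colonies held 7.14 ± 0.14, 7.71 ± 0.23 and 7.99 ± 0.066 FPKM, which did not differ from DMSO (0.12 ± 0.06, adjusted p = 0.125) and lay below BLU667 (-0.21 ± 0.06, adjusted p = 0.0165). The acute RET call was lost with only the groups compared in the fit (adjusted p = 0.0677), the call against BLU667 without BLU667 replicate 2 (0.146) or with colony means as 3 replicates (0.283), and the comparison with DMSO was called under quantile normalization (0.17, adjusted p = 0.0473). CCDC6, the other fusion partner (ENSG00000108091, chromosome 10, 59788763 to 59906656, minus strand), stayed below the filter, at 0.51 ± 0.31 FPKM in DMSO, 0.354 ± 0.02 in BLU667 and 0.102 ± 0.03, 0.141 ± 0.08 and 0.981 ± 0.12 in the colonies. Gene totals do not separate fusion from normal transcripts.

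TERT, the catalytic subunit of telomerase, fell from 1.55 ± 0.068 to 0.106 ± 0.08 FPKM in BLU667 (-1.20 ± 0.14, adjusted p = 0.000149) and stood at 0.2 ± 0.12, 0.304 ± 0.031 and 0.519 ± 0.042 FPKM in the colonies (-0.93 ± 0.12 against DMSO, adjusted p = 0.000317). Against BLU667 the colonies' TERT was not called (0.27 ± 0.12, adjusted p = 0.0733), although 4 alternatives called it, among them a pseudocount of 0.1 (1.07, adjusted p = 0.035) and voom on recovered reads (1.70, adjusted p = 0.0108). CDKN2A†, which encodes the cell-cycle inhibitors p16 and ARF, was 52.7 ± 7.3 FPKM in DMSO and 56.1 ± 1.6 in BLU667 (0.09 ± 0.13, adjusted p = 0.557), a difference called once the GC trend was removed (0.31, adjusted p = 0.00411). It fell to 12.2 ± 1, 15.8 ± 2.5 and 26.1 ± 0.63 FPKM in the colonies (-1.56 ± 0.10 against DMSO, adjusted p = 9.9e-06, and -1.65 ± 0.10 against BLU667, adjusted p = 4.73e-06).

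**Figure D1:**
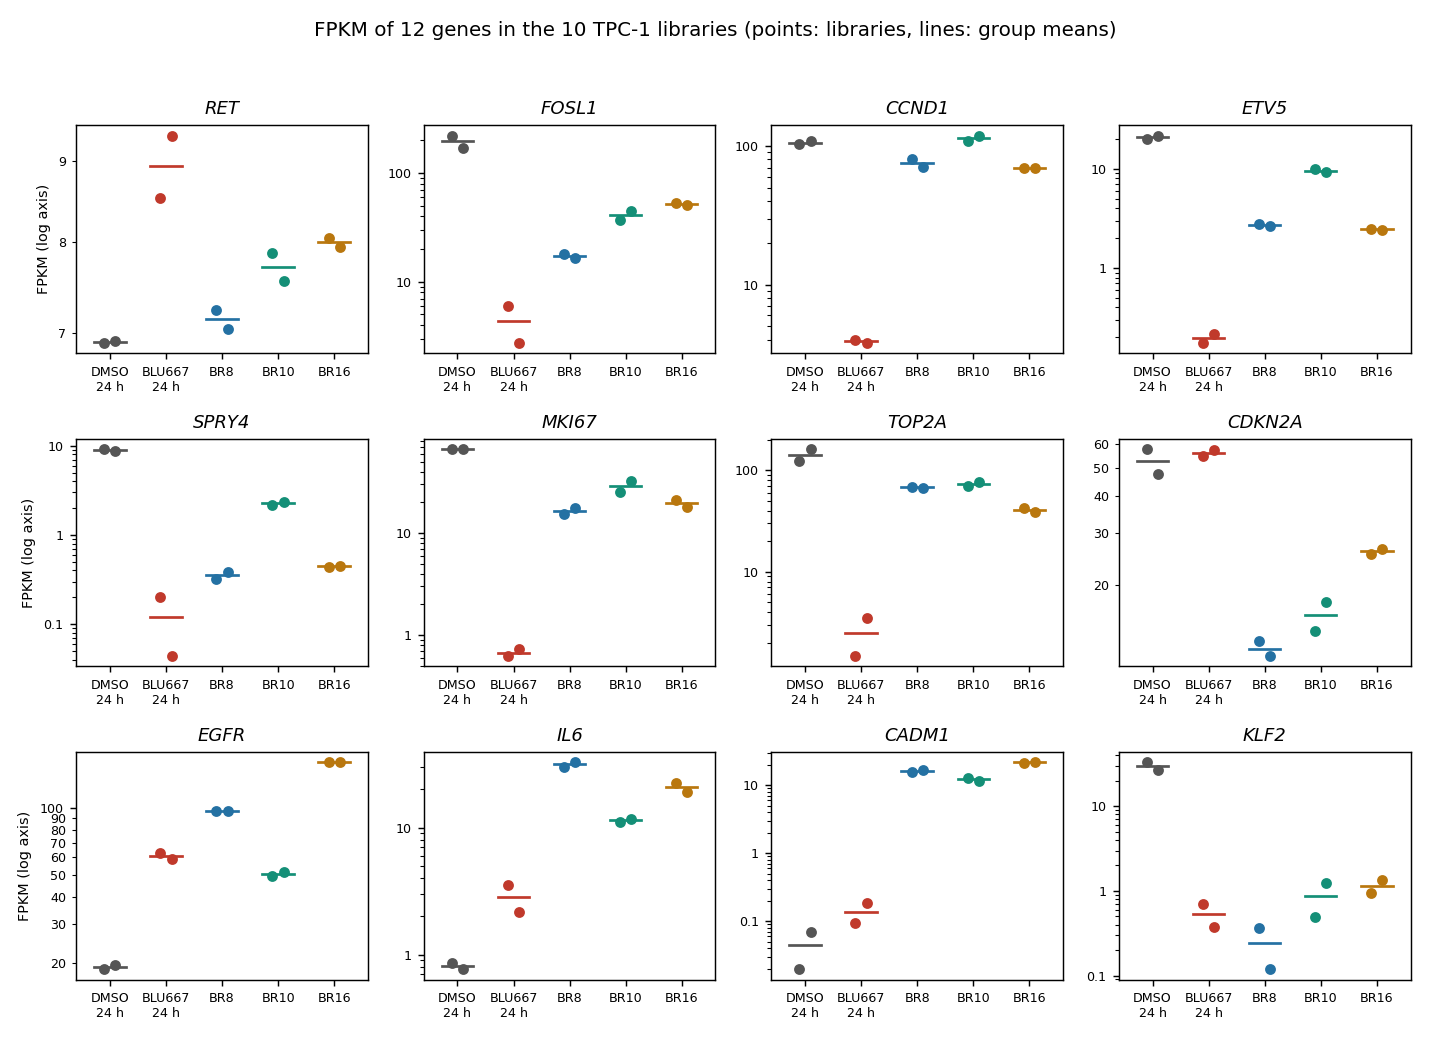
FPKM (log axes) of 12 genes in the 5 groups, with each point a library (2 per group) and each line the group mean. MKI67 went from 66.3 FPKM in DMSO to 0.672 in BLU667 and 16.4, 28.8 and 19.7 in BR8, BR10 and BR16, while RET stayed between 6.91 and 8.93.

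The comparison of BLU667 with DMSO asked which transcripts differed after 24 h of the RET inhibitor. The largest rises were those of SERPINF2 (0.236 ± 0.009 to 41.6 ± 8.5 FPKM, 5.09 ± 0.13), the alpha-2-antiplasmin gene, EDN1 (0.113 ± 0.028 to 32.2 ± 5.6 FPKM, 4.89 ± 0.16), which encodes the vasoconstrictor endothelin-1, PDZK1 (1.22 ± 0.038 to 64.6 ± 8 FPKM, 4.88 ± 0.12), a scaffold of membrane transporters, and KCNJ13† (0.0771 ± 0.019 to 26.4 ± 1.6 FPKM, 4.67 ± 0.11), a potassium channel. CD24 (68 ± 1.9 to 1150 ± 29 FPKM, 4.06 ± 0.082), a cell-surface glycoprotein, and BMF† (0.146 ± 0.059 to 19.9 ± 5.1 FPKM, 4.17 ± 0.16), a pro-apoptotic BH3-only protein, also rose. So did the histone gene HIST1H2AC (4.27 ± 0.11), the single-strand DNA binding protein gene NABP1† (4.21 ± 0.10), the phosphate transporter SLC17A1 (4.07 ± 0.089) and the folate receptor FOLR1 (3.95 ± 0.12). The largest falls were in MYBL2 (76.7 ± 9.1 to 0.463 ± 0.098 FPKM, -5.73 ± 0.12), a cell-cycle transcription factor, NOX5† (60 ± 5.1 to 0.24 ± 0.064 FPKM, -5.62 ± 0.10), an NADPH oxidase, TOP2A (143 ± 28 to 2.48 ± 1.4 FPKM, -5.42 ± 0.25), the topoisomerase of dividing cells, and G0S2 (235 ± 84 to 4.61 ± 1.8 FPKM, -5.39 ± 0.32), an inhibitor of lipolysis. MKI67 (66.3 ± 0.49 to 0.672 ± 0.072 FPKM, -5.33 ± 0.13), the Ki-67 proliferation marker, FOSL1 (195 ± 36 to 4.34 ± 2.3 FPKM, -5.26 ± 0.26), an AP-1 subunit, and EMP1 (35.3 ± 0.74 to 0.0657 ± 0.011 FPKM, -5.09 ± 0.09), a membrane protein, fell as well, with the organic anion carrier SLCO4A1† (-5.20 ± 0.17), the mitotic kinase PBK (-5.12 ± 0.14) and the ribonucleotide reductase subunit RRM2† (-4.97 ± 0.14). Adjusted p for these 20 genes lay between 3.74e-08 and 3.14e-06.

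In the limma fit, 8380 of 13927 genes were called, 4038 higher and 4342 lower in BLU667, of which 1233 and 1556 changed by at least 2-fold. The median SE of a log2 change was 0.12. Camera called 10 of the gene lists, 7 higher and 3 lower, and none of these calls held with an estimated correlation between genes. Leaving out DMSO replicate 2 left 6 called lists, and voom on recovered reads called 16.

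Of the 22 tested genes induced by ERK signalling, 1 was higher, 19 lower and 2 not called (same adjusted over the list alone). Among the falls were CCND1† (-4.45 ± 0.089), which encodes cyclin D1, and ETV5† (-4.18 ± 0.079), an ETS transcription factor. Its median was -2.02 (camera adjusted p = 5.14e-08, adjusted p = 0.334 with an estimated correlation). All 30 genes of S phase and mitosis were lower (the same count adjusted over the list alone), including UBE2C (-4.74 ± 0.11), a ubiquitin-conjugating enzyme of mitotic exit. Its median was -3.98 (camera adjusted p = 1.89e-19, adjusted p = 0.334 with an estimated correlation). For genes induced by FOXO factors, 6 were higher, 1 lower and 5 not called (same adjusted over the list alone). The list was not called, and its median was 0.73 (camera adjusted p = 0.0601, adjusted p = 0.337 with an estimated correlation). PIK3IP1† (2.89 ± 0.13), an inhibitor of phosphoinositide 3-kinase, CITED2 (2.55 ± 0.086) and the atypical cyclin CCNG2 (2.12 ± 0.12) rose, whereas the Krüppel-like factor KLF2 (-4.34 ± 0.22) fell. Among the 17 tested p53 targets, 5 were higher, 7 lower and 5 not called (same adjusted over the list alone), with TP53INP1 (2.34 ± 0.12) higher and the death receptor FAS† (-1.50 ± 0.16) lower. The p53 list was not called. Its median was -0.18 (camera adjusted p = 0.762, adjusted p = 0.805 with an estimated correlation).

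Of 18 tested receptor tyrosine kinases other than RET, 10 were higher, 4 lower and 4 not called (same adjusted over the list alone). Its median was 0.66 (camera adjusted p = 0.0765, adjusted p = 0.48 with an estimated correlation). EPHB2† (2.90 ± 0.18) and the epidermal growth factor receptor EGFR† (1.62 ± 0.072) rose. Among their ligands, 7 were higher, 6 lower and 4 not called (same adjusted over the list alone). Its median was 0.21, its mean -0.02 and the test direction higher (camera adjusted p = 0.756, adjusted p = 0.805 with an estimated correlation). PDGFD† (2.42 ± 0.12) was higher, while the EGFR ligand TGFA (-1.97 ± 0.10) was lower. Every tested hedgehog gene, 5 of 5, was higher (the same count adjusted over the list alone). Its median was 0.75 (camera adjusted p = 0.0269, adjusted p = 0.337 with an estimated correlation). These included the transcription factor GLI2 (0.86 ± 0.11), the signal transducer SMO† (0.81 ± 0.096) and the receptor PTCH1† (0.75 ± 0.12). In the Wnt list, 3 were higher, 5 lower and 3 not called (same adjusted over the list alone), with LGR5† (-1.63 ± 0.12) lower and WNT5B (1.27 ± 0.099) higher. Its median was -0.23 (camera adjusted p = 0.667, adjusted p = 0.787 with an estimated correlation). Among Notch genes, 2 were higher, 7 lower and 1 not called (same adjusted over the list alone). Its median was -0.60 (camera adjusted p = 0.232, adjusted p = 0.572 with an estimated correlation). The Notch target HES1 (-3.43 ± 0.13) fell and the ligand JAG1† (2.64 ± 0.075) rose.

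Among 17 tested genes of the IL6, JAK and STAT pathway, 7 were higher, 6 lower and 4 not called (same adjusted over the list alone). Its median was 0.19 (camera adjusted p = 0.576, adjusted p = 0.638 with an estimated correlation). The feedback inhibitor SOCS3 (-2.78 ± 0.16) fell, and the receptor LIFR† (2.5 ± 0.12) rose. Of 12 NF-kB targets and inflammatory cytokines, 9 were higher, 0 lower and 3 not called (same adjusted over the list alone), including the chemokine CCL2 (1.89 ± 0.15), the NF-kB subunit RELB (1.83 ± 0.14) and the inhibitor NFKBIA (1.69 ± 0.14). Its median was 1.18 (camera adjusted p = 0.00527, adjusted p = 0.405 with an estimated correlation). Of 15 interferon-stimulated genes, 10 were higher, 2 lower and 3 not called (same adjusted over the list alone). Its median was 0.58 (camera adjusted p = 0.0269, adjusted p = 0.334 with an estimated correlation). STAT2 (1.64 ± 0.097), the RNA sensor DDX58 (1.5 ± 0.13), IFI44L (1.27 ± 0.13) and IFI6 (1.22 ± 0.13) rose. For antigen presentation, 8 were higher, 1 lower and 3 not called (same adjusted over the list alone). Its median was 0.64 (camera adjusted p = 0.0188, adjusted p = 0.337 with an estimated correlation). The class I genes HLA-E (1.07 ± 0.10) and HLA-B† (0.77 ± 0.12) rose and the peptide transporter TAP2† (-1.03 ± 0.12) fell.

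Of 13 mesenchymal genes, 8 were higher, 2 lower and 3 not called (same adjusted over the list alone), among them the gelatinase MMP2† (2.44 ± 0.10), fibronectin FN1 (1.71 ± 0.13) and the transcription factor SNAI2 (1.40 ± 0.13), all higher. Their median was 0.42 (camera adjusted p = 0.0452, adjusted p = 0.337 with an estimated correlation), and camera lost the call with the GC trend removed (adjusted p = 0.0537). For 6 epithelial genes, 1 was higher, 3 lower and 2 not called (1 higher and 4 lower adjusted over the list alone). Its median was -0.37 (camera adjusted p = 0.573, adjusted p = 0.638 with an estimated correlation). The junction protein TJP1 (1.68 ± 0.10) rose, and the keratin KRT18† (-1.56 ± 0.14) fell. Collagens, laminins and matrix glycoproteins divided as follows: 12 were higher, 3 lower and 4 not called (13 higher and 3 lower adjusted over the list alone). Its median was 0.71 (camera adjusted p = 0.00802, adjusted p = 0.376 with an estimated correlation). The basement membrane collagen COL4A1 (2.73 ± 0.078) and COL12A1 (2.45 ± 0.071) rose and the laminin chain LAMB3† (-2.55 ± 0.14) fell. Among YAP and TAZ targets, 9 were higher, 4 lower and 3 not called (same adjusted over the list alone). Its median was 0.64 (camera adjusted p = 0.064, adjusted p = 0.337 with an estimated correlation). TGFB2† (2.36 ± 0.10) and the LIM protein AJUBA† (1.71 ± 0.088) rose and the ectonucleotidase NT5E (-3.69 ± 0.17) fell. In the TGF-beta list, 8 were higher, 3 lower and 5 not called (9 higher and 3 lower adjusted over the list alone), with the ligand TGFB1† (1.94 ± 0.17) higher and BHLHE40† (-1.21 ± 0.13) lower. Its median was 0.46 (camera adjusted p = 0.0665, adjusted p = 0.337 with an estimated correlation).

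Among glycolysis and hypoxia-inducible genes, 3 were higher, 13 lower and 0 not called (same adjusted over the list alone). Its median was -1.50 (camera adjusted p = 0.000733, adjusted p = 0.337 with an estimated correlation). The enolase ENO2 (-2.38 ± 0.15), hexokinase HK2† (-2.11 ± 0.096), the glucose carrier SLC2A1† (-2.07 ± 0.14) and lactate dehydrogenase LDHA (-2.01 ± 0.079) fell. Of 20 tested ATF4 and unfolded protein response genes, 4 were higher, 12 lower and 4 not called (same adjusted over the list alone). Its median was -0.60 (camera adjusted p = 0.0601, adjusted p = 0.337 with an estimated correlation). The folate enzyme MTHFD2† (-2.73 ± 0.10) fell and HERPUD1 (2.43 ± 0.071) rose. For sterol synthesis and uptake, 8 were higher, 4 lower and 8 not called (same adjusted over the list alone), with the synthase HMGCS1† (1.26 ± 0.15) and the oxidase MSMO1 (1.03 ± 0.16) higher. Its median was 0.02 (camera adjusted p = 0.572, adjusted p = 0.795 with an estimated correlation). Among ABC transporters, 5 were higher, 1 lower and 2 not called (same adjusted over the list alone). Its median was 0.43 (camera adjusted p = 0.0601, adjusted p = 0.376 with an estimated correlation). ABCC4 (2.02 ± 0.097) and the drug exporter ABCB1 (1.20 ± 0.092) rose.

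Of 12 tested BCL2 family genes, 3 were higher, 5 lower and 4 not called (3 higher and 6 lower adjusted over the list alone). Its median was -0.25, its mean 0.10 and the test direction lower (camera adjusted p = 0.642, adjusted p = 0.753 with an estimated correlation). BCL2L11† (1.64 ± 0.094), which encodes the BH3-only protein BIM, rose, and the effector BAK1† (-1.36 ± 0.16) and the survival factor MCL1† (-1.25 ± 0.074) fell. Among lysosome and autophagy genes, 12 were higher, 6 lower and 3 not called (same adjusted over the list alone). Its median was 0.41 (camera adjusted p = 0.0601, adjusted p = 0.405 with an estimated correlation). The sialidase NEU1 (1.81 ± 0.11) rose and the galactosidase GLA (-1.27 ± 0.092) fell. Of 6 tested thyroid differentiation genes, 2 were higher, 2 lower and 2 not called (same adjusted over the list alone). Its median was -0.13, its mean 0.27 and the test direction higher (camera adjusted p = 0.816, adjusted p = 0.822 with an estimated correlation). The transcription factor GLIS3† (2.25 ± 0.067) rose, and HHEX (-1.19 ± 0.096) fell.

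No immune, endothelial or erythroid marker passed the filter, and 1 C cell gene, ENO2, and 1 squamous gene, SFN, did, so these lists had no set test. ENO2 was lower and SFN, an inhibitor of the cell cycle, was called lower, at 0.655 ± 0.11 FPKM in DMSO and 0 in both BLU667 libraries (adjusted p = 0.0235). Of 5 fibroblast markers, 2 were higher, 1 lower and 2 not called (same adjusted over the list alone), with PDGFRB (1.95 ± 0.14) and COL1A1 (0.71 ± 0.14) higher and podoplanin PDPN (-1.15 ± 0.13) lower. Its median was 0.38 (camera adjusted p = 0.573, adjusted p = 0.757 with an estimated correlation). Among the 13 mitochondrial transcripts, 1 was higher, 1 lower and 11 not called (1 higher and 0 lower adjusted over the list alone), with MT-ND4L† (0.68 ± 0.13) higher and MT-CO3† (-0.77 ± 0.22) lower. Its median was -0.18 (camera adjusted p = 0.841, adjusted p = 0.949 with an estimated correlation). Of 30 ribosomal protein genes, 14 were higher, 2 lower and 14 not called (same adjusted over the list alone). Its median was 0.28 (camera adjusted p = 0.0452, adjusted p = 0.48 with an estimated correlation). RPLP1 (0.71 ± 0.16) rose and RPL8† (-0.81 ± 0.25) fell. Alternatives ended the call of SFN (adjusted p = 0.101 without DMSO replicate 1 and 0.11 with array weights), MT-ND4L (adjusted p = 0.283 with no filter on low values), MT-CO3 (adjusted p = 0.0722 without DMSO replicate 1 and 0.412 with no filter on low values) and RPL8 (adjusted p = 0.103 without BLU667 replicate 2 and 0.107 with only the groups compared in the fit).

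Comparing adapted colonies with 24 h of DMSO could not separate BLU667 exposure from time in culture or colony selection. The largest rises shared by the 3 colonies were in EDN2 (0.225 ± 0.1 to 89.1 ± 14, 14.3 ± 0.063 and 137 ± 6.8 FPKM, 5.55 ± 0.091), an endothelin, NOV (0.113 ± 0.074 to 60.1 ± 1.7, 27.4 ± 0.46 and 60.4 ± 0.71 FPKM, 5.41 ± 0.073), the matricellular protein CCN3, PDZK1IP1 (1.35 ± 0.21 to 118 ± 6.7, 43.6 ± 1.7 and 152 ± 3 FPKM, 5.31 ± 0.073), a membrane protein that binds PDZK1, and IL32† (0.973 ± 0.045 to 90 ± 19, 34.1 ± 3.2 and 80.5 ± 0.66 FPKM, 5.01 ± 0.14), a cytokine. CADM1 (0.0442 ± 0.035 to 16.1 ± 1, 12.2 ± 0.71 and 21.7 ± 0.2 FPKM, 4.04 ± 0.069), an adhesion molecule, and IL6† (0.812 ± 0.068 to 31.6 ± 1.7, 11.4 ± 0.47 and 20.8 ± 2.2 FPKM, 3.51 ± 0.13), the cytokine, also rose, with the vesicle protein MAL2† (4.81 ± 0.11), IGFBP7† (4.49 ± 0.10) and the lectin CLEC4E (3.63 ± 0.13). The largest falls were those of G0S2 (235 ± 84 to 0.968 ± 0.3, 3.03 ± 1.3 and 0.672 ± 0.25 FPKM, -6.61 ± 0.26), NOX5† (60 ± 5.1 to 0.0187 ± 0.0071, 0.225 ± 0.025 and 0.0119 ± 0.0041 FPKM, -5.82 ± 0.084), EMP1 (35.3 ± 0.74 to 0.0664 ± 0.019, 2.66 ± 0.1 and 0.115 ± 0.06 FPKM, -4.48 ± 0.074) and TGM2† (286 ± 35 to 6.84 ± 0.32, 31 ± 4.9 and 8.6 ± 1.3 FPKM, -4.42 ± 0.13), a transglutaminase. KLF2 (-4.19 ± 0.18), LAPTM5 (-4.03 ± 0.13), the keratin KRT81 (-3.88 ± 0.18) and SIGLEC15 (-3.71 ± 0.11) fell as well. Metallothionein MT1E, a metal-binding protein, went from 15.2 ± 5.4 FPKM in DMSO to 0 reads in all 6 adapted libraries, which makes it at least 571-fold lower, and PDPN from 25.5 ± 1.3 to 1.85 ± 0.51 and 1.35 ± 0.21 FPKM in BR8 and BR10 and 0 in BR16, where it was at least 1072-fold lower. Floors of this kind take 3 reads over the group at 0 and cover counting error only. Adjusted p here lay between 6.43e-09 and 1.36e-06. MAL2 rose mainly in BR8 and BR16, uncalled with colony means as replicates (adjusted p = 0.117).

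In the limma fit, 6848 genes were called, 3183 higher and 3665 lower in the adapted colonies, of which 673 and 569 changed by at least 2-fold, and the median SE was 0.10. With the 3 colony means as replicates of 1 adapted group, the count was 1540 (818 higher, 722 lower). Single colonies gave 7144 calls in BR8 (3346 higher, 3798 lower), 5680 in BR10 (2680 and 3000) and 6342 in BR16 (3049 and 3293). The BR10 count was 3557 without BR10 replicate 1 and 3324 with only BR10 and DMSO in the fit. In the same direction in all 3 colonies, 2768 genes were called, 1452 higher and 1316 lower, where independent lists would share 334.4. Because the colonies share the DMSO libraries, part of that excess may come from them. Camera called 10 lists, 6 higher and 4 lower, none of which held with an estimated correlation.

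ERK-induced genes divided as follows: 2 were higher, 18 lower and 2 not called (3 higher and 19 lower adjusted over the list alone). Its median was -1.12 (camera adjusted p = 2.17e-06, adjusted p = 0.25 with an estimated correlation). FOSL1 (-2.51 ± 0.21), the feedback inhibitor SPRY4 (-2.42 ± 0.089) and the ETS factor ETV1 (-2.34 ± 0.10) fell. By colony, their median was -1.48 in BR8, -0.76 in BR10 and -1.30 in BR16. Of 30 S phase and mitosis genes, 0 were higher, 28 lower and 2 not called (same adjusted over the list alone). Its median was -1.02 (camera adjusted p = 1.31e-11, adjusted p = 0.25 with an estimated correlation). The kinase PLK1† (-1.68 ± 0.07), MKI67 (-1.62 ± 0.10), cyclin B1 CCNB1 (-1.54 ± 0.13) and the checkpoint kinase BUB1 (-1.54 ± 0.084) fell, and the list median was -0.93, -0.77 and -1.26 in the 3 colonies. In the FOXO list, 6 were higher, 5 lower and 1 not called (6 higher and 6 lower adjusted over the list alone), with KLF4 (2.07 ± 0.072) and CITED2 (1.97 ± 0.071) higher. Its median was 0.19 (camera adjusted p = 0.605, adjusted p = 0.744 with an estimated correlation). Among p53 targets, 5 were higher, 4 lower and 8 not called (same adjusted over the list alone). Its median was -0.06 (camera adjusted p = 0.998, adjusted p = 0.999 with an estimated correlation). GDF15 (-2.08 ± 0.15) fell and the repair gene XPC† (0.53 ± 0.11) rose. Replicates made of the colony means left no call for XPC (adjusted p = 0.101).

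Receptor tyrosine kinases moved both ways: 5 were higher, 5 lower and 8 not called (same adjusted over the list alone). Its median was 0.09 (camera adjusted p = 0.676, adjusted p = 0.863 with an estimated correlation). EGFR† (19.2 ± 0.55 to 97.2 ± 0.51, 50.5 ± 1.8 and 161 ± 0.082 FPKM, 2.21 ± 0.058) and FGFR2 (0.0833 ± 0.047 to 2.03 ± 0.19, 2.66 ± 0.25 and 3.16 ± 0.27 FPKM, 1.73 ± 0.10) rose, and FGFR4 (-1.47 ± 0.091) fell. Among ligands, 8 were higher, 5 lower and 4 not called (same adjusted over the list alone). Its median was 0.05 (camera adjusted p = 0.427, adjusted p = 0.644 with an estimated correlation). PDGFB (0.802 ± 0.18 to 22.4 ± 2.4, 11.1 ± 0.17 and 27.6 ± 0.74 FPKM, 3.48 ± 0.092), a platelet-derived growth factor, rose and TGFA (-1.78 ± 0.083) fell. Of the 5 tested hedgehog genes, 2 were higher, 3 lower and 0 not called (same adjusted over the list alone), with GLI2 (1.58 ± 0.093) higher and GLI3 (-0.72 ± 0.071) lower. Its median was -0.53, its mean 0.02 and the test direction lower (camera adjusted p = 0.605, adjusted p = 0.795 with an estimated correlation). Among Wnt genes, 5 were higher, 2 lower and 4 not called (6 higher and 2 lower adjusted over the list alone). Its median was 0.20 (camera adjusted p = 0.176, adjusted p = 0.419 with an estimated correlation). The ligand WNT5B (2.40 ± 0.081) rose and LGR5† (-1.11 ± 0.098) fell. In the Notch list, 2 were higher, 5 lower and 3 not called (same adjusted over the list alone), with the ligand JAG1† (2.35 ± 0.061) higher and HES1 (-2.22 ± 0.11) lower. Its median was -0.25 (camera adjusted p = 0.599, adjusted p = 0.781 with an estimated correlation). With the colony means as 3 replicates, no call remained for GLI3 and LGR5 (adjusted p from 0.114 to 0.155).

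Of the 12 NF-kB targets and inflammatory cytokines, 11 were higher, 0 lower and 1 not called (same adjusted over the list alone). Its median was 1.28 (camera adjusted p = 5.92e-06, adjusted p = 0.25 with an estimated correlation). TNF (2.86 ± 0.12), CCL2 (2.13 ± 0.12), the neutrophil chemokine CXCL8 (2.04 ± 0.26) and RELB (1.92 ± 0.12) rose, and the list median was 1.74 in BR8, 0.46 in BR10 and 1.45 in BR16. In the IL6, JAK and STAT list, 8 were higher, 6 lower and 3 not called (same adjusted over the list alone), with JAK1† (1.46 ± 0.079) higher and SOCS3 (-2.37 ± 0.13) lower. Its median was 0.06 (camera adjusted p = 0.557, adjusted p = 0.644 with an estimated correlation). Interferon-stimulated genes counted as follows: 9 were higher, 1 lower and 5 not called (9 higher and 2 lower adjusted over the list alone). Its median was 0.59 (camera adjusted p = 0.0238, adjusted p = 0.25 with an estimated correlation). IFIT3 (1.13 ± 0.10), IFI6 (1.06 ± 0.10) and IFIH1 (0.87 ± 0.11) rose. Of 12 antigen presentation genes, 10 were higher, 0 lower and 2 not called (same adjusted over the list alone). Its median was 0.81 (camera adjusted p = 9.94e-05, adjusted p = 0.25 with an estimated correlation). The class I genes HLA-B† (1.67 ± 0.098) and HLA-C† (1.01 ± 0.11) and their light chain B2M (0.91 ± 0.073) rose. Colony means used as 3 replicates left uncalled CCL2, CXCL8 and IFI6 (adjusted p from 0.0815 to 0.117).

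Matrix genes were mostly higher: 14 were higher, 2 lower and 3 not called (same adjusted over the list alone). Its median was 0.86 (camera adjusted p = 1.75e-05, adjusted p = 0.25 with an estimated correlation). COL4A1 (34.7 ± 1.7 to 385 ± 17, 94.2 ± 4.3 and 419 ± 2.2 FPKM, 2.80 ± 0.064), the proteoglycan BGN (2.29 ± 0.093), COL12A1 (2.21 ± 0.058) and COL7A1† (2.20 ± 0.10) rose. Of the 16 YAP and TAZ targets, 10 were higher, 3 lower and 3 not called (same adjusted over the list alone). Its median was 0.73 (camera adjusted p = 0.0188, adjusted p = 0.25 with an estimated correlation). WWC1 (2.37 ± 0.067), which encodes KIBRA, the matricellular CYR61 (2.12 ± 0.092) and CRIM1† (1.42 ± 0.062) rose and NT5E (-3.34 ± 0.14) fell. For mesenchymal genes, 4 were higher, 3 lower and 6 not called (same adjusted over the list alone), with TGFBI (2.59 ± 0.20) higher and SNAI1 (-1.31 ± 0.11) lower. Its median was 0.17 (camera adjusted p = 0.575, adjusted p = 0.644 with an estimated correlation). For the 6 tested epithelial genes, 4 were higher, 0 lower and 2 not called (5 higher and 0 lower adjusted over the list alone). Its median was 0.36 (camera adjusted p = 0.0975, adjusted p = 0.25 with an estimated correlation). OCLN (0.65 ± 0.094) and KRT8† (0.42 ± 0.10) rose, and without colony BR16 the KRT8 difference turned to -0.09. In the TGF-beta list, 7 were higher, 4 lower and 5 not called (same adjusted over the list alone), with PMEPA1† (2.10 ± 0.21) and TGFB2† (1.35 ± 0.085) higher. Its median was 0.11 (camera adjusted p = 0.151, adjusted p = 0.353 with an estimated correlation). The call was lost for KRT8 (adjusted p = 0.064 without DMSO replicate 2 and 0.565 without colony BR16). When the 3 colony means served as replicates, the call was lost for BGN, TGFBI, SNAI1, OCLN, KRT8 and TGFB2 (adjusted p from 0.0652 to 0.589).

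Glycolysis and hypoxia-inducible genes were mostly lower: 2 were higher, 13 lower and 1 not called (same adjusted over the list alone). Its median was -0.67 (camera adjusted p = 0.000189, adjusted p = 0.25 with an estimated correlation). PFKFB4† (-1.36 ± 0.10), SLC2A1† (-1.29 ± 0.11) and NDRG1 (-1.22 ± 0.088) fell, and the glucose carrier SLC2A3 went from 1.56 ± 0.13 FPKM to 0 reads in all 6 adapted libraries, at least 343-fold lower. Of the ATF4 and unfolded protein response genes, 5 were higher, 9 lower and 6 not called (same adjusted over the list alone), with the pseudokinase TRIB3 (-1.62 ± 0.089) lower and STC2 (1.38 ± 0.057) higher. Its median was -0.21 (camera adjusted p = 0.5, adjusted p = 0.644 with an estimated correlation). In the sterol list, 5 were higher, 3 lower and 12 not called (same adjusted over the list alone). Its median was 0.12 (camera adjusted p = 0.338, adjusted p = 0.72 with an estimated correlation). HMGCS1† (1.01 ± 0.12) rose, and the sterol list was called in BR10 (median 0.47, adjusted p = 0.000296, adjusted p = 0.352 with an estimated correlation). ABC transporters split as follows: 5 were higher, 2 lower and 1 not called (same adjusted over the list alone), with ABCB1 (1.69 ± 0.075) higher and ABCA2 (-0.82 ± 0.12) lower. Its median was 0.60 (camera adjusted p = 0.107, adjusted p = 0.419 with an estimated correlation). The 3 colony means as replicates gave no call for HMGCS1 and ABCA2 (adjusted p from 0.0819 to 0.179).

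Lysosome and autophagy genes were called higher: 13 were higher, 3 lower and 5 not called (same adjusted over the list alone). Its median was 0.40 (camera adjusted p = 0.00452, adjusted p = 0.25 with an estimated correlation). LAMP1 (0.97 ± 0.067), NEU1 (0.90 ± 0.091) and WIPI1† (0.83 ± 0.085) rose and CTSD† (-0.92 ± 0.22) fell. In the BCL2 family, 7 were higher, 3 lower and 2 not called (same adjusted over the list alone). Its median was 0.28 (camera adjusted p = 0.165, adjusted p = 0.353 with an estimated correlation). The BH3-only gene BIK (2.45 ± 0.21) and the survival factors BCL2 (1.85 ± 0.076) and BCL2A1 (1.25 ± 0.15) rose and BAK1† (-0.71 ± 0.13) fell, although BCL2A1 stood at 0.081 ± 0.11 FPKM in BR10 against 4.36 ± 0.55 in BR8. Among thyroid differentiation genes, 3 were higher, 1 lower and 2 not called (3 higher and 2 lower adjusted over the list alone). Its median was 0.26 (camera adjusted p = 0.375, adjusted p = 0.506 with an estimated correlation). THRB† (1.49 ± 0.083) and the thyroid transcription factor PAX8† (0.61 ± 0.13) rose. Not called under an alternative were CTSD (adjusted p = 0.0869 without DMSO replicate 1) and PAX8 (adjusted p = 0.0876 without colony BR16). Replicates made of the colony means left no call for CTSD, BCL2A1, BAK1 and PAX8 (adjusted p from 0.0721 to 0.436).

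ENO2 (-0.50 ± 0.13), the C cell gene tested, was lower, and SFN, the squamous gene tested, was higher, at 0.655 ± 0.11 FPKM in DMSO and 10.4 ± 1.6, 2.96 ± 1.5 and 11.6 ± 1.4 in the colonies (adjusted p = 2.73e-05). Of the fibroblast markers, 2 were higher, 2 lower and 1 not called (same adjusted over the list alone). Its median was 0.27, its mean -0.68 and the test direction lower (camera adjusted p = 0.81, adjusted p = 0.893 with an estimated correlation). LUM, a matrix proteoglycan, had 0 reads in DMSO, 5.52 ± 1.3 FPKM in BR8 and less than 0.1 in BR10 and BR16, and COL1A1 (0.50 ± 0.12) rose. Among mitochondrial transcripts, 0 were higher, 9 lower and 4 not called (0 higher and 10 lower adjusted over the list alone). Its median was -0.75 (camera adjusted p = 0.0315, adjusted p = 0.644 with an estimated correlation). MT-ND1 (-1.05 ± 0.24), MT-ND3 (-1.01 ± 0.25) and MT-CYB (-0.82 ± 0.21) fell. Their median was -1.02 in BR8, -1.28 in BR10 and 0.10 in BR16. Ribosomal protein genes divided as follows: 4 were higher, 3 lower and 23 not called (3 higher and 2 lower adjusted over the list alone), with RPL8† (-0.73 ± 0.21) lower. Its median was -0.05 (camera adjusted p = 0.998, adjusted p = 0.999 with an estimated correlation). Some settings left uncalled ENO2 (adjusted p = 0.0534 without DMSO replicate 1), COL1A1 (adjusted p = 0.0573 without DMSO replicate 2 and 0.305 without colony BR16), MT-ND1 (adjusted p = 0.0708 without DMSO replicate 2 and 0.0739 with no filter on low values), MT-ND3 (adjusted p = 0.0851 without DMSO replicate 2 and 0.0793 with no filter on low values), MT-CYB (adjusted p = 0.0921 without DMSO replicate 2 and 0.106 with no filter on low values) and RPL8 (adjusted p = 0.128 without DMSO replicate 1 and 0.068 with no filter on low values). With the colony means as 3 replicates, no call remained for LUM, ENO2, COL1A1, MT-ND1, MT-ND3, MT-CYB and RPL8 (adjusted p from 0.253 to 0.442).

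Comparing adapted colonies with BLU667 could not separate exposure time from colony selection. The largest rises shared by the colonies included NOV (0.279 ± 0.12 to 60.1 ± 1.7, 27.4 ± 0.46 and 60.4 ± 0.71 FPKM, 5.22 ± 0.073), MYBL2 (0.463 ± 0.098 to 31.8 ± 1.4, 35.9 ± 4.8 and 39.8 ± 0.00023 FPKM, 4.65 ± 0.095), CCND1† (3.89 ± 0.13 to 75.9 ± 7.5, 114 ± 7 and 69.6 ± 0.46 FPKM, 4.12 ± 0.072) and CADM1 (0.138 ± 0.064 to 16.1 ± 1, 12.2 ± 0.71 and 21.7 ± 0.2 FPKM, 3.92 ± 0.069), and genes of S phase and mitosis: the histone chaperone ASF1B† (4.50 ± 0.089), RRM2† (4.22 ± 0.11), TOP2A (4.17 ± 0.20), the kinase CDK1 (3.84 ± 0.093), the ubiquitin ligase adaptor DTL (3.83 ± 0.11) and FAM111B (3.82 ± 0.10). The largest falls included SERPINF2 (41.6 ± 8.5 to 0.235 ± 0.01, 0.312 ± 0.043 and 0.501 ± 0.0041 FPKM, -4.97 ± 0.11), KCNJ13† (26.4 ± 1.6 to 0.00955 ± 0.014, 0.0949 ± 0.071 and 0.127 ± 0.034 FPKM, -4.67 ± 0.09), BMF† (19.9 ± 5.1 to 0.821 ± 0.0096, 0.774 ± 0.19 and 0.488 ± 0.061 FPKM, -3.61 ± 0.13) and FOLR1 (17.9 ± 2.7 to 0.264 ± 0.017, 0.292 ± 0.041 and 0.628 ± 0.12 FPKM, -3.76 ± 0.10), with the quinolinate enzyme QPRT† (-3.78 ± 0.064), the actin bundler ESPN† (-3.71 ± 0.11), the dipeptidase DPEP1 (-3.58 ± 0.11), lymphotoxin beta LTB (-3.55 ± 0.18) and the cation carrier SLC47A2 (-3.46 ± 0.086). MT1E went from 54.1 ± 7.6 FPKM in BLU667 to 0 reads in all 6 adapted libraries, at least 2034-fold lower. Adjusted p for these 20 genes lay between 1.55e-08 and 1.3e-06.

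In the limma fit, 8507 genes were called, 4514 higher and 3993 lower in the adapted colonies, of which 1074 and 777 changed by at least 2-fold, and the median SE was 0.10. With the colony means as 3 replicates, 3656 genes were called, 1977 higher and 1679 lower. Camera called 5 lists, 3 higher and 2 lower, and none held with an estimated correlation. Leaving out either BR10 replicate left 3 lists, as did a fit without the variance trend or with array weights.

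Of the ERK-induced genes, 17 were higher, 3 lower and 2 not called (same adjusted over the list alone). Its median was 0.62 (camera adjusted p = 0.00344, adjusted p = 0.422 with an estimated correlation). FOSL1 (2.74 ± 0.21), the phosphatase DUSP5 (2.19 ± 0.15) and ETV5† (0.197 ± 0.03 to 2.72 ± 0.095, 9.59 ± 0.44 and 2.46 ± 0.024 FPKM, 2.10 ± 0.065) rose. All 30 S phase and mitosis genes were higher (the same count adjusted over the list alone), MKI67 (0.672 ± 0.072 to 16.4 ± 1.5, 28.8 ± 4.9 and 19.7 ± 2.2 FPKM, 3.72 ± 0.10) among them. Its median was 2.83 (camera adjusted p = 4.71e-18, adjusted p = 0.403 with an estimated correlation). FOXO-induced genes were called lower: 1 was higher, 10 lower and 1 not called (same adjusted over the list alone). Its median was -0.66 (camera adjusted p = 0.00487, adjusted p = 0.422 with an estimated correlation). CDKN1B (-1.83 ± 0.062), which encodes the cell-cycle inhibitor p27, CCNG2 (-1.42 ± 0.10) and FOXO1† (-1.06 ± 0.14) fell, whereas KLF4 (2.07 ± 0.072) rose. Among p53 targets, 5 were higher, 5 lower and 7 not called (same adjusted over the list alone), with TP53INP1 (-1.86 ± 0.095) lower and FAS† (1.44 ± 0.13) higher. Its median was -0.09 (camera adjusted p = 0.765, adjusted p = 0.853 with an estimated correlation).

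Among receptor tyrosine kinases, 6 were higher, 11 lower and 1 not called (same adjusted over the list alone). Its median was -0.37 (camera adjusted p = 0.227, adjusted p = 0.82 with an estimated correlation). PDGFRB (-3.27 ± 0.11) fell and ROR1 (1.03 ± 0.071) rose. For their ligands, 8 were higher, 5 lower and 4 not called (same adjusted over the list alone), with PDGFB (2.07 ± 0.092) higher and VEGFC (-1.19 ± 0.10) lower. Its median was 0.35 (camera adjusted p = 0.485, adjusted p = 0.82 with an estimated correlation). In the hedgehog list, 1 was higher, 4 lower and 0 not called (same adjusted over the list alone). Its median was -1.02 (camera adjusted p = 0.0852, adjusted p = 0.564 with an estimated correlation). SMO† (-1.34 ± 0.078) fell and GLI2 (0.72 ± 0.093) rose. Wnt genes counted as follows: 7 were higher, 0 lower and 4 not called (same adjusted over the list alone), with WNT7B (1.65 ± 0.13) and WNT5B (1.14 ± 0.081) higher. Its median was 0.52 (camera adjusted p = 0.0852, adjusted p = 0.422 with an estimated correlation). For Notch genes, 5 were higher, 4 lower and 1 not called (same adjusted over the list alone), with HES4 (1.82 ± 0.25) and JAG2† (1.36 ± 0.11) higher. Its median was 0.20 (camera adjusted p = 0.666, adjusted p = 0.853 with an estimated correlation). Colony means used as 3 replicates left uncalled GLI2 and HES4 (adjusted p from 0.0622 to 0.0948).

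In the IL6, JAK and STAT list, 8 were higher, 5 lower and 4 not called (same adjusted over the list alone). Its median was 0.05 (camera adjusted p = 0.968, adjusted p = 0.967 with an estimated correlation). IL6† (2.45 ± 0.13) rose and CEBPD (-1.74 ± 0.12) fell. NF-kB targets and cytokines divided as follows: 5 were higher, 2 lower and 5 not called (same adjusted over the list alone), with TNF (1.68 ± 0.12) and the adhesion molecule ICAM1† (1.32 ± 0.11) higher. Its median was 0.35 (camera adjusted p = 0.534, adjusted p = 0.853 with an estimated correlation). Of interferon-stimulated genes, 4 were higher, 5 lower and 6 not called (4 higher and 7 lower adjusted over the list alone). Its median was -0.16 (camera adjusted p = 0.711, adjusted p = 0.846 with an estimated correlation). IFI44L (-1.57 ± 0.10) fell and OAS3 (1.06 ± 0.077) rose. For antigen presentation genes, 6 were higher, 1 lower and 5 not called (same adjusted over the list alone), with TAP2† (0.97 ± 0.10) and HLA-B† (0.89 ± 0.098) higher. Its median was 0.20 (camera adjusted p = 0.465, adjusted p = 0.836 with an estimated correlation). When the 3 colony means served as replicates, the call was lost for ICAM1 and HLA-B (adjusted p from 0.108 to 0.253).

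Mesenchymal genes were mostly lower, without a call for the list: 3 were higher, 8 lower and 2 not called (same adjusted over the list alone). Its median was -0.44 (camera adjusted p = 0.102, adjusted p = 0.422 with an estimated correlation). SNAI1 (-2.68 ± 0.11) fell and TGFBI (2.22 ± 0.20) rose. Among the epithelial genes, 5 were higher, 1 lower and 0 not called (same adjusted over the list alone), with CLDN1 (1.59 ± 0.20) higher and TJP1 (-1.41 ± 0.085) lower. Its median was 0.76 (camera adjusted p = 0.15, adjusted p = 0.422 with an estimated correlation). In the matrix list, 8 were higher, 3 lower and 8 not called (same adjusted over the list alone). Its median was 0.07 (camera adjusted p = 0.473, adjusted p = 0.853 with an estimated correlation). The laminin chain LAMB3† (1.83 ± 0.12) rose and COL5A2 (-1.83 ± 0.076) fell. For YAP and TAZ targets, 6 were higher, 7 lower and 3 not called (7 higher and 7 lower adjusted over the list alone), with tissue factor F3 (1.74 ± 0.096) higher and TGFB2† (-1.01 ± 0.085) lower. Its median was -0.02, its mean 0.08 and the test direction lower (camera adjusted p = 0.765, adjusted p = 0.863 with an estimated correlation). TGF-beta genes split evenly, as 6 were higher, 6 lower and 4 not called (same adjusted over the list alone). Its median was 0.05, its mean -0.05 and the test direction lower (camera adjusted p = 0.765, adjusted p = 0.853 with an estimated correlation). TGFB1† (-2.41 ± 0.14) fell and PMEPA1† (1.17 ± 0.21) rose. The 3 colony means as replicates gave no call for TGFBI, TGFB2 and PMEPA1 (adjusted p from 0.0609 to 0.136).

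Glycolysis and hypoxia-inducible genes were called higher: 12 were higher, 3 lower and 1 not called (same adjusted over the list alone). Its median was 0.62 (camera adjusted p = 0.0474, adjusted p = 0.564 with an estimated correlation). ENO2 (1.88 ± 0.13), PGK1† (1.47 ± 0.074) and HK2† (1.18 ± 0.078) rose and NDRG1 (-1.66 ± 0.088) fell, and camera lost the call with the GC trend removed (adjusted p = 0.0591). Of the ATF4 and unfolded protein response genes, 11 were higher, 2 lower and 7 not called (12 higher and 2 lower adjusted over the list alone), with MTHFD2† (2.10 ± 0.084) higher and HERPUD1 (-2.03 ± 0.058) lower. Its median was 0.33 (camera adjusted p = 0.0852, adjusted p = 0.422 with an estimated correlation). In the sterol list, 7 were higher, 4 lower and 9 not called (7 higher and 3 lower adjusted over the list alone). Its median was 0.09 (camera adjusted p = 0.765, adjusted p = 0.937 with an estimated correlation). PMVK (0.83 ± 0.17) rose and FDFT1† (-0.75 ± 0.061) fell. For ABC transporters, 3 were higher, 2 lower and 3 not called (same adjusted over the list alone), with ABCC3 (0.75 ± 0.077) higher and ABCA1 (-1.39 ± 0.082) lower. Its median was 0.00 (camera adjusted p = 0.922, adjusted p = 0.956 with an estimated correlation). Replicates made of the colony means left no call for FDFT1 and ABCC3 (adjusted p from 0.14 to 0.197).

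BCL2 family genes counted as follows: 9 were higher, 2 lower and 1 not called (same adjusted over the list alone). Its median was 0.71 (camera adjusted p = 0.0852, adjusted p = 0.422 with an estimated correlation). BIK (2.40 ± 0.21) rose and BCL2L11† (-1.29 ± 0.077) fell, and BCL2A1 went from 0 reads in BLU667 to a mean of 2.05 FPKM over the colonies, at least 26-fold higher, a floor that does not hold for BR10 (0.081 ± 0.11 FPKM). Among lysosome and autophagy genes, 6 were higher, 8 lower and 7 not called (same adjusted over the list alone), with GLA (1.17 ± 0.075) higher and NEU1 (-0.91 ± 0.091) lower. Its median was 0.03, its mean 0.00 and the test direction lower (camera adjusted p = 0.851, adjusted p = 0.937 with an estimated correlation). In the thyroid list, 3 were higher, 2 lower and 1 not called (same adjusted over the list alone). Its median was 0.30 (camera adjusted p = 0.765, adjusted p = 0.853 with an estimated correlation). HHEX (0.99 ± 0.079) rose and GLIS3† (-1.15 ± 0.055) fell. With the colony means as 3 replicates, no call remained for BCL2A1 (adjusted p = 0.138).

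SFN, the squamous gene tested, went from 0 reads in BLU667 to a mean of 8.32 FPKM over the colonies, at least 128-fold higher. That floor does not hold for BR10, the colony with the lowest level. ENO2, the C cell gene tested, was higher. Fibroblast markers divided as follows: 2 were higher, 2 lower and 1 not called (same adjusted over the list alone), with PDGFRB (-3.27 ± 0.11) and PDPN (-2.67 ± 0.11) lower and LUM (0.57 ± 0.13) and the smooth muscle actin ACTA2† (0.47 ± 0.14) higher. Its median was -0.21 (camera adjusted p = 0.412, adjusted p = 0.82 with an estimated correlation). LUM was above BLU667 (0.305 ± 0.083 FPKM) in BR8 alone, and with voom on recovered reads its difference turned to -0.42 (adjusted p = 0.549). Of the mitochondrial transcripts, 0 were higher, 7 lower and 6 not called (same adjusted over the list alone), with MT-ND1 (-0.87 ± 0.24) and MT-ND4† (-0.85 ± 0.20) lower. Its median was -0.54 (camera adjusted p = 0.0761, adjusted p = 0.836 with an estimated correlation). Ribosomal protein genes were called lower: 1 was higher, 12 lower and 17 not called (0 higher and 11 lower adjusted over the list alone). Its median was -0.18 (camera adjusted p = 0.0496, adjusted p = 0.641 with an estimated correlation). RPLP1 (-0.94 ± 0.13), RPL10† (-0.74 ± 0.13) and RPLP0 (-0.66 ± 0.074) fell and RPL11 (0.70 ± 0.26) rose. A changed setting removed the call of LUM (adjusted p = 0.549 with voom on recovered reads), ACTA2 (adjusted p = 0.112 without BLU667 replicate 1 and 0.601 without colony BR16), MT-ND1 (adjusted p = 0.169 without BLU667 replicate 1 and 0.107 with no filter on low values), MT-ND4 (adjusted p = 0.0871 without BLU667 replicate 1 and 0.172 with no filter on low values) and RPL11 (adjusted p = 0.196 without BLU667 replicate 2 and 0.265 without colony BR16). Colony means used as 3 replicates left uncalled LUM, ACTA2, MT-ND1, MT-ND4, RPL10 and RPL11 (adjusted p from 0.0845 to 0.598).

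**Figure D2:**
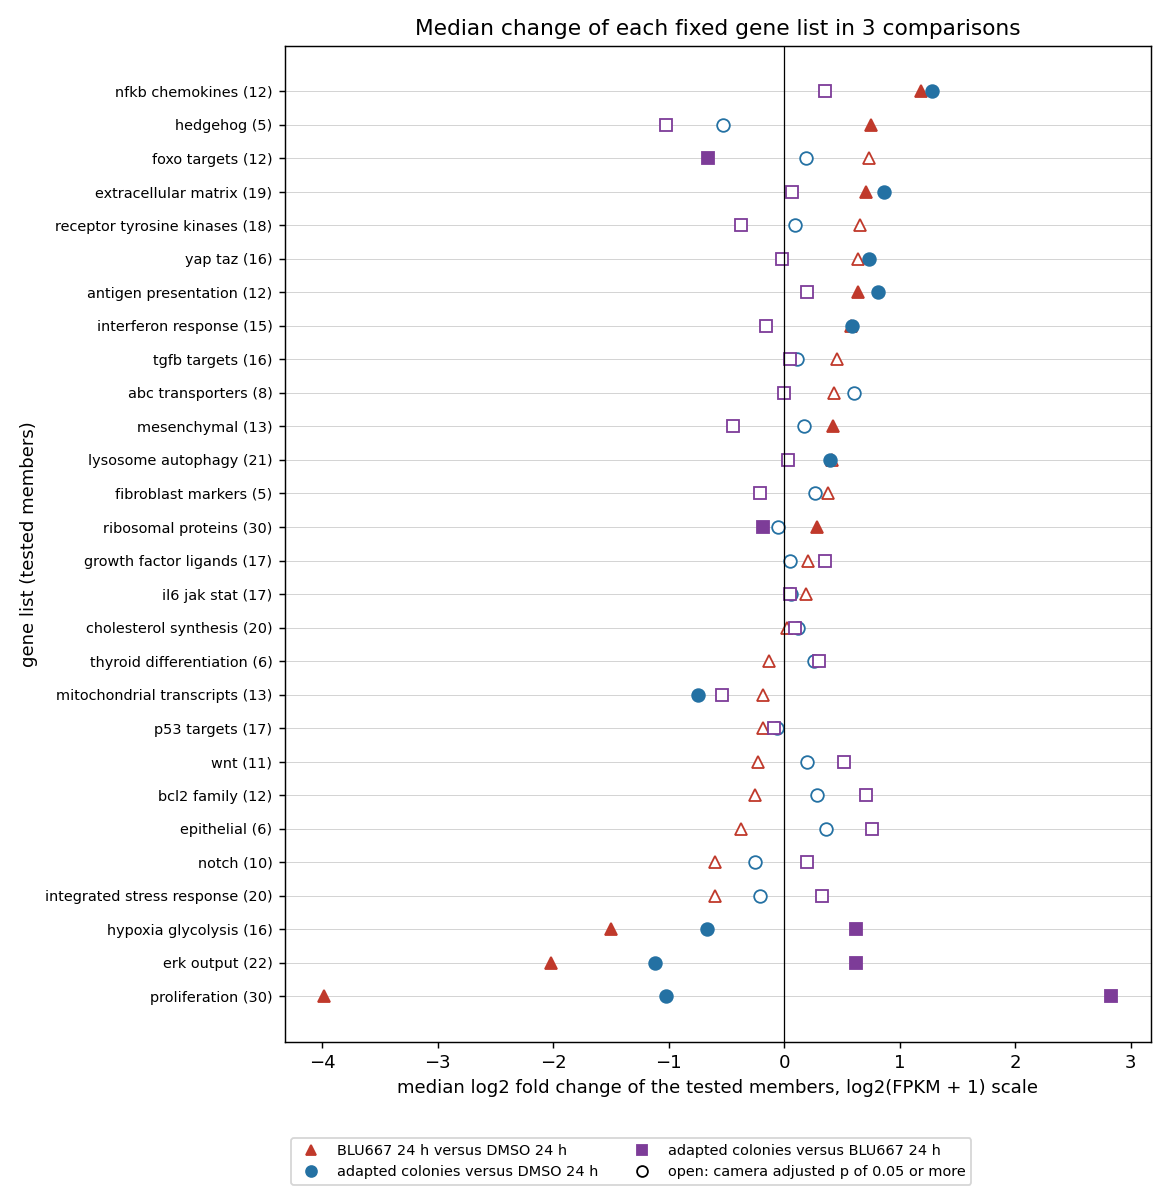
Median log2 change of the tested members of each gene list (one line of points per list, log2 scale on the horizontal axis) in the 3 comparisons, filled where camera adjusted p was below 0.05 and open otherwise. S phase and mitosis genes lay at -3.98 in BLU667 against DMSO, -1.02 in the adapted colonies against DMSO and 2.83 in the adapted colonies against BLU667.

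MKI67, CCND1 and ETV5 fell in BLU667 and were higher in the colonies than in BLU667, whereas SERPINF2, KCNJ13 and FOLR1 rose in BLU667 and were lower in the colonies. Of the 8380 genes called in BLU667 against DMSO, 5873 (70.1%) differed in the opposite direction between the adapted colonies and BLU667, 2786 of the higher and 3087 of the lower genes. Among these 5873, the colonies remained called against DMSO in the acute direction for 2306, were not called for 2967 and were called in the other direction for 600. Among genes called with at least a 2-fold acute change, the median adapted change was 36.4% of the acute one. Independent lists (2565 opposed) ignore the shared BLU667 libraries, and 100 simulations of unchanged groups (mean 0.03, at most 1) hold few calls. Neither is a baseline.

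EGFR, COL4A1, JAG1 and PDGFD were higher, and NOX5, EMP1, G0S2 and KLF2 lower, than DMSO both at 24 h and in the colonies. In the same direction in both comparisons, 4399 genes were called, 1946 higher and 2453 lower, where independent lists would share 922.9 and 1143. In opposite directions, 336 were higher at 24 h and lower in the colonies and 264 the reverse. A further 1849 genes, among them KLF4 and CDKN2A, were called in the colonies and not at 24 h, 973 higher and 876 lower, which does not show that they were unchanged at 24 h. Log2 changes correlated across genes at r = 0.601, and simulated unchanged groups with the same shared DMSO libraries gave 0.611, so this r carries no information on its own. Their covariance was 0.353 against 0.017 simulated, a difference of 0.336. Simulated calls in both (at most 1) were few by construction. Part of the excess may come from the shared controls, and the 2 DMSO libraries were not split between the comparisons.

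**Figure D3:**
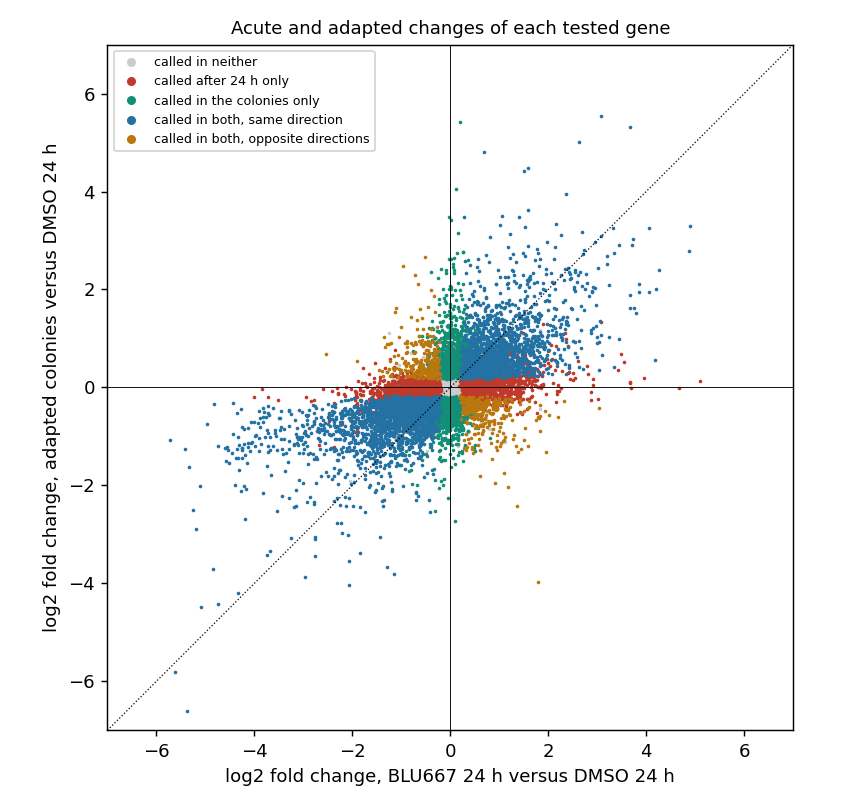
Log2 change in the adapted colonies against DMSO (vertical axis) plotted over log2 change in BLU667 against DMSO (horizontal axis), with each point 1 of 13927 tested genes. The 4399 genes called in the same direction in both comparisons lie in the upper right and lower left, and r across genes was 0.601.

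Comparisons among BR8, BR10 and BR16 asked how far the adapted colonies differed from each other. BR8 stood apart by fibronectin, with FN1 at 21.1 ± 1.1 FPKM against 378 ± 3.9 in BR10 and 338 ± 9.7 in BR16 (log2 difference from the mean of the other two -4.02, F test adjusted p = 3.55e-06). BR8 was also lower for the vesicle protein VAMP8 (-2.98) and the keratin KRT81 (-2.38), and LRRC61†, at 8.5 ± 1.3 FPKM in DMSO, had 0 reads in BR8, at least 266-fold lower. It was higher for LUM (2.61, adjusted p = 4.13e-05), the annexin ANXA8L1† (2.59), the teneurin TENM2 (2.57) and the adhesion molecule ICAM1† (2.40). BR10 was lower for MAL2†, at 1.04 ± 0.062 FPKM against 139 ± 2.9 in BR8 and 128 ± 0.96 in BR16 (-6.04, adjusted p = 6.66e-07), TMEM171 (-3.29), TMEM40 (-3.20) and TENM2 (-3.15). BR10 was higher for the claudin CLDN16 (64.7 ± 0.1 FPKM, 2.73, adjusted p = 1.57e-05), the protease inhibitor SLPI (2.69) and LAPTM5 (2.64), and the glutamate carrier SLC1A1 stood at 4.24 ± 0.12 FPKM in BR10, 0 in BR8 and 0.00705 ± 0.01 in BR16.

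BR16 was higher for the carrier SLC16A4† (15.5 ± 0.25 FPKM, 3.16, adjusted p = 3.87e-06), LRFN4† (2.83), the proteoglycan BGN (2.79) and the parathymosin gene PTMS (2.79), and lower for CLDN16 (-2.92), the neuropeptide gene NMU (-2.23), SLPI (-2.04) and MILR1 (-1.76). Leaving out BR16 replicate 2 ended the SLPI call between BR8 and BR16 (adjusted p = 0.0544). A moderated F test called 8092 genes (58.1%) as differing among colonies, and 5236 without BR16 replicate 2. Pairwise, 3172 genes were called between BR8 and BR10, 6771 between BR8 and BR16 and 6003 between BR10 and BR16. Between BR8 and BR10 the count was 1820 without BR10 replicate 2, between BR8 and BR16 it was 3987 without BR16 replicate 2, and between BR10 and BR16 it was 3269 without BR10 replicate 1. With the GC trend of each library removed, 98% of the calls between BR8 and BR10, 52.1% of those between BR8 and BR16 and 61% of those between BR10 and BR16 were kept.

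ERK-induced genes were lower in BR8 than in BR10 (median difference -0.71, 0 higher and 17 lower, camera adjusted p = 8.94e-10, adjusted p = 0.274 with an estimated correlation) and higher in BR10 than in BR16 (0.35, 11 higher and 2 lower, adjusted p = 0.00734, adjusted p = 0.414 with an estimated correlation). NF-kB targets and cytokines were higher in BR8 than in BR10 (1.1, 12 higher and 0 lower, adjusted p = 2.49e-08, adjusted p = 0.274 with an estimated correlation) and lower in BR10 than in BR16 (-1.29, 1 higher and 9 lower, adjusted p = 0.000185, adjusted p = 0.414 with an estimated correlation). Sterol synthesis genes were lower in BR8 than in BR10 (-0.58, 0 higher and 14 lower, adjusted p = 1.08e-06, adjusted p = 0.274 with an estimated correlation) and higher in BR10 than in BR16 (0.82, 12 higher and 2 lower, adjusted p = 0.0011, adjusted p = 0.414 with an estimated correlation). S phase and mitosis genes were higher in BR10 than in BR16 (0.58, 21 higher and 0 lower, adjusted p = 2.46e-05, adjusted p = 0.414 with an estimated correlation). Mitochondrial transcripts were lower in BR8 (-1.08, adjusted p = 0.00403, adjusted p = 0.784 with an estimated correlation) and BR10 (-1.21, adjusted p = 0.000272, adjusted p = 0.446 with an estimated correlation) than in BR16. These camera calls held with the GC trend removed. Calls that did not were receptor tyrosine kinases and Notch genes between BR8 and BR16 (adjusted p = 0.164 and 0.138), IL6 pathway, antigen presentation, Notch and lysosome genes between BR10 and BR16 (0.301, 0.0907, 0.404 and 0.185) and ribosomal protein genes between BR8 and BR10 (0.056).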

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

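The patterns weighed here, removal of the GC trend and the fits without BR16 were chosen after seeing the data. So were the tests of a short drug response, of the whole chromosome as the only cause and of single libraries in the mitochondrial pattern.

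The colonies differed in 8092 genes, 534 of them higher than DMSO in 1 colony and lower in another, and 110 of the 131 named genes of the adapted comparison differed among colonies. Calls numbered 3172 between BR8 and BR10 but 6771 and 6003 between BR16 and BR8 or BR10, a ratio of 2.01. With the GC trend removed they numbered 4236, 4925 and 5021, so that the ratio of 1.17 came from fewer calls against BR16 and from more between BR8 and BR10, and it lay between the 1.1 predicted if that trend were the cause and the 1.5 predicted if it were not. Leaving out 1 colony library gave 1.51 to 2.96 for 5 of the 6 libraries, above 1.5, and 1.38 without BR16 replicate 2. Both BR16 libraries lay apart on the third component (44.23 and 45.29, others at most 5.14), which argues against a single library. A GC trend and true distance cannot be told apart, as 1.17 lay between the bounds. BR10 replicates also differed in GC trend (Spearman -0.45).

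Chromosome 8 genes lay below other genes in all 3 colonies against DMSO. With the GC trend removed the smallest of the 3 differences was -0.34, which argues against that trend, and at 24 h of BLU667 the difference was -0.04, which argues against a short drug response as the cause of the whole pattern. At 20 to 40 Mb the colonies stood at -0.77, -0.72 and -0.77 and the bin at 24 h at -0.24 (95% interval -0.36 to 0.01), above every colony's interval, while at 120 to 140 Mb it was -0.23 (-0.36 to 0), where a response of that size and a later fall cannot be told apart because the intervals overlap. Intervals at 20 to 40 and 60 to 80 Mb, the widest gap, lay at least 0.26 apart in each colony. That argues against fewer copies of the whole chromosome as sole cause. Whether they add to loss of part cannot be told. All intervals reflect genes, not libraries, and colonies share DMSO. The highest bin, 60 to 80 Mb in BR10, stood at -0.07 (-0.29 to -0.03).

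Mitochondrial transcripts were lower than DMSO in BR8 and BR10 and not in BR16. With the GC trend removed the higher of the 2 medians was -1.1, which argues against that trend. The highest share of mitochondrial reads in a BR8 or BR10 library was 3.64%, below the lowest of the DMSO and BR16 libraries, which argues against a single library. Whether mitochondrial DNA, transcription or RNA recovery differed stays open.

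Between BR8 and BR10 the list medians differed by -0.71 for ERK-induced genes, -0.18 for S phase and mitosis, 0.28 for the IL6 pathway, 1.1 for NF-kB targets, 0.43 for interferon-stimulated genes, 0.38 for antigen presentation, 0.37 for matrix, -0.58 for sterol synthesis, -0.24 for hypoxia-inducible, 0.24 for ATF4 and unfolded protein response and -0.22 for ribosomal protein genes. BR8 and BR16 differed by 0.26 for S phase and mitosis, -0.36 for receptor tyrosine kinases, -0.36 for YAP and TAZ targets, -0.75 for Notch, -0.32 for FOXO-induced, -1.08 for mitochondrial and -0.32 for ribosomal protein genes. BR10 and BR16 differed by 0.35 for ERK-induced genes, 0.58 for S phase and mitosis, -0.44 for the IL6 pathway, -1.29 for NF-kB targets, -0.50 for antigen presentation, -0.74 for matrix, 0.82 for sterol synthesis, -0.54 for Notch, -0.30 for lysosome and -1.21 for mitochondrial genes. None of these list differences held with an estimated correlation (adjusted p from 0.274 to 0.784). With the GC trend removed, the calls also ended for ribosomal protein genes between BR8 and BR10, for receptor tyrosine kinases and Notch genes between BR8 and BR16, and for IL6 pathway, antigen presentation, Notch and lysosome genes between BR10 and BR16.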

How the results depend on the processing

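GC trend removal, voom, array weights and the fits without BR16 were chosen after seeing the data, and the other settings before the data were examined. Unless stated, the cause of a shift was not tested. With 2 libraries per group, single libraries carried much of the evidence. Required to reach an absolute log2 change of 1, the calls fell in number by construction: 2789 for BLU667 against DMSO, 1242 for the adapted colonies against DMSO and 1851 against BLU667; 2025, 1225 and 1617 for BR8, BR10 and BR16 against DMSO; 571 (BR8 and BR10), 1169 (BR8 and BR16) and 1059 (BR10 and BR16) between colonies. The same minimum gave 552 genes in all 3 colonies, 1829 among colonies, 1189 opposed and 656 shared by short and long exposure. Colony means as 3 replicates gave 1540 calls against DMSO and 3656 against BLU667, and ended 77 of 260 named results. Only BR10 and DMSO in the fit gave 3324. For gene lists, an estimated correlation left 0, 0 and 0 called in the 3 main comparisons, and fry called 21, 21 and 20. Voom called 16 lists in BLU667 against DMSO, and 3 lists were called in the adapted colonies against BLU667 without the variance trend and with array weights.

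Leaving out 1 library, where the lone sample of a group was assumed to vary like the other groups, gave 7081 to 8236 calls for BLU667 against DMSO, 6044 to 6686 for the adapted colonies against DMSO and 6817 to 9102 against BLU667. Against DMSO the ranges were 5510 to 7387 (BR8), 3557 to 5924 (BR10) and 4315 to 6905 (BR16). Between colonies they were 1820 to 4144 (BR8 and BR10), 3987 to 7551 (BR8 and BR16) and 3269 to 6908 (BR10 and BR16). Further ranges were 2100 to 2817 in all 3 colonies, 5236 to 8969 among colonies, 4634 to 5987 opposed and 3856 to 4262 shared. Lists called ranged from 6 to 14, 9 to 10 and 3 to 6. Single omissions that moved a count most gave, between BR8 and BR10, 1860, 2092, 2031 and 1820; between BR8 and BR16, 4489, 4361 and 3987; between BR10 and BR16, 3269, 3651 and 3351.

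The sign turned for LUM in the adapted colonies against BLU667 with voom (-0.42, adjusted p = 0.549) and for KRT8 against DMSO without BR16 (-0.09, adjusted p = 0.565). A replicate block gave 8142, 6501 and 8265 calls in the main comparisons, while correlations between equal replicate numbers lay from -0.163 to 0.109, so the numbers do not pair.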

Other observations

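The gene families below were chosen after their values were seen, as were the genes at 0 reads and the chromosome regions. Histone genes were higher in BLU667 than in DMSO (17 higher and 1 lower of 25, median 1.5, camera adjusted p = 8.55e-06, adjusted p = 0.0789 with an estimated correlation) and lower in the adapted colonies than in BLU667 (0 and 16, -0.76, adjusted p = 8.32e-05, adjusted p = 0.114 with an estimated correlation). Proteasome subunits were lower in BLU667 (2 and 29 of 39, -1.15, adjusted p = 3.85e-07, adjusted p = 0.0789 with an estimated correlation) and higher in the colonies than in BLU667 (28 and 1, 0.80, adjusted p = 2.1e-06, adjusted p = 0.114 with an estimated correlation). Of the 19 families looked at, camera called 9 in BLU667 against DMSO, 4 in the adapted colonies against DMSO and 8 against BLU667, and 0 in each with an estimated correlation. Because the families were picked on their values, these p are too small to be taken as tests.

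In all 6 adapted libraries, 7 genes with a DMSO mean of at least 1 FPKM had 0 reads, among them EMC10 (at least 1068-fold lower), CHST1 (197) and the transcription factor FOXA2 (143). At 0 reads in DMSO, 14 genes had an adapted mean of at least 1 FPKM, among them NCALD (at least 516-fold higher), VTCN1 (186) and MAF (180).

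With the GC trend removed, medians of 20 Mb bins against DMSO differed from other genes in BR8, BR10 and BR16 by 0.80, 0.09 and 0.14 (chromosome 7, 60 to 80 Mb), -0.67, -0.04 and 0.05 (chromosome 7, 120 to 140 Mb), -0.77, -0.04 and -0.04 (chromosome 2, 220 to 240 Mb) and 0.54, 0.06 and 0.23 (chromosome 17, 80 to 100 Mb). Chromosome 10 lay lower in all 3 only at 100 to 120 Mb (-0.33, -0.29, -0.32) and 120 to 140 Mb (-0.25, -0.20, -0.27). There, 24 h of BLU667 gave -0.06 and -0.25.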
